A study of Mus musculus with 6 samples.

How the data were processed

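RNA from isolated luminal uterine epithelium of mice at 3.5 days post coitum was measured on a single Illumina mouse bead chip that held all 6 arrays. Per the labels, 3 arrays carried Control samples (replicates A, B and C) and 3 carried samples with a conditional knockout of Alk3 (replicates D, E and F, here CKO). Alk3 is another name for Bmpr1a, a type I receptor for bone morphogenetic proteins (BMPs). In the CKO, Cre made from the progesterone receptor locus (Pgr) removes a floxed part of Bmpr1a that includes 1 exon. Per the labels' protocols, the mice had a mixed background of C57BL/6J and 129S5/SvEvBrd, and uterine tissue was frozen and homogenised for RNA. The labels do not say how the epithelium was isolated, nor that each array came from a separate animal, so p-values measure the spread between these samples. Chip positions A to C held Control and D to F held CKO, so position and group cannot be told apart.

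Per the file headers, the deposited scanner tables give for each of 45281 probes a bead-averaged intensity on a linear scale, a detection p-value and the number of beads. These intensities were neither background-subtracted nor normalised between arrays. The authors also deposited a table of processed intensity values. Set against the same arrays' raw values, these were background-subtracted, quantile-normalised and linear, with a median of 6.4 on each array. The software behind both is not given in the sources used here. The median raw signal ran from 79.7 to 87.6, the median number of beads per probe from 39 to 42, and the number of probes above background (detection p-value under 0.05) from 16620 to 17536. The number of arrays limits the precision.

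Raw intensities were background-corrected by normexp with negative controls inferred from the detection p-values, given an offset of 16, quantile-normalised and put on the log2 scale (neqc in limma 3.58.1, R 4.3.3). The offset makes fold changes of dim genes smaller than they are. Probes above background on at least 3 of the 6 arrays were kept, which left 17291. A total of 29370 probes were named by RefSeq accession and 6962 by symbol through a RefSeq gene table of GRCm38.p6. Another 8927 kept the name in the file, and 22 with no name or several were left out. The table served only for names and for which genes neighbour each other. The probe with the highest mean signal stood for its gene, which gave 11939 genes.

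CKO was compared with Control by limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Adjusted p-values for genes are from this fit. Lists of genes were tested with limma's camera at a preset correlation of 0.01, adjusted over 20 function lists and, separately, over 13 cell type marker lists. Each was tested again with an estimated correlation and with fry. Each Bmpr1a probe also had an exact two-sided permutation test, which with 3 against 3 arrays cannot go below 0.1. A gene below background on every array of a group has only a bound there. Its fold is given as "at least", from the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal above background and the probe's own.

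The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took Bmpr1a and Pgr; the genes past the test with groups that did not overlap (up to 12 a direction, or the 10 with the smallest p where none passed, skipping clone and predicted names); up to 4 passing members of each list, or up to 2 where none passed; and a fixed set of BMP, steroid and implantation genes. It left open what to do when genes pass in 1 direction only; here the 10 lower genes with the smallest p were taken as well. Erdr1, Thap4, Arrdc3 and Kit were named after their values were seen, as were the genes named for array E.

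The steps were tested on simulated data made from the means and spread of the 11939 genes, in 20 runs with 200 changed genes each. Of genes changed 1.5-fold 0.40% were recovered, of those changed 2-fold 17.6%, of those changed 4-fold 84.7% and of those changed 8-fold 95.2%. False calls made up 5.54% of all calls. The simulation drew genes independently of each other, which real genes are not. The alternatives were other background corrections (normexp without controls and an offset of 50, or none), median scaling, cyclic loess, the authors' deposited intensity values, no filter, a filter of detection p-value under 0.01 on all 6 arrays, the mean of a gene's probes, a variance trend with robust fitting, array weights, and leaving out each array. A fit with the mean of the stroma markers as a covariate was added after the data were seen.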

Results

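Gene expression in luminal uterine epithelium at 3.5 days post coitum was compared between 3 CKO and 3 Control samples, 1 array each. The comparison asked how loss of the BMP receptor Alk3 changes this epithelium at the time when the uterus becomes ready for the embryo. Correlations between arrays over 11939 genes averaged 0.968 within Control, 0.947 within CKO and 0.959 between the groups, so samples of the same group were not uniformly more alike than samples of different groups. CKO array E had the lowest mean correlation with the other arrays, 0.936.

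Bmpr1a, the targeted gene, was measured by 2 probes. The brighter gave a normalised log2 signal of 8.60 ± 0.31 (SD, n = 3) in CKO and 9.19 ± 0.20 (SD, n = 3) in Control, a difference of -0.60 (95% confidence interval -1.12 to -0.07). All 3 CKO arrays lay below all 3 Control arrays, with an exact permutation p of 0.1, the smallest that 3 against 3 allows. The adjusted p was 0.977, so the gene did not pass. The other probe gave 6.40 ± 0.69 (SD, n = 3) in CKO and 6.91 ± 0.27 (SD, n = 3) in Control, with groups that overlapped and an exact permutation p of 0.3. Whether either probe lies in the deleted exon could not be determined without probe sequences, and a probe outside it would not check the deletion. Pgr, which carries Cre in the CKO, differed by -0.43 with an SE of 0.56 and did not pass. Its sign changed when Control replicate B or CKO replicate E was left out.

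**Figure D1:**
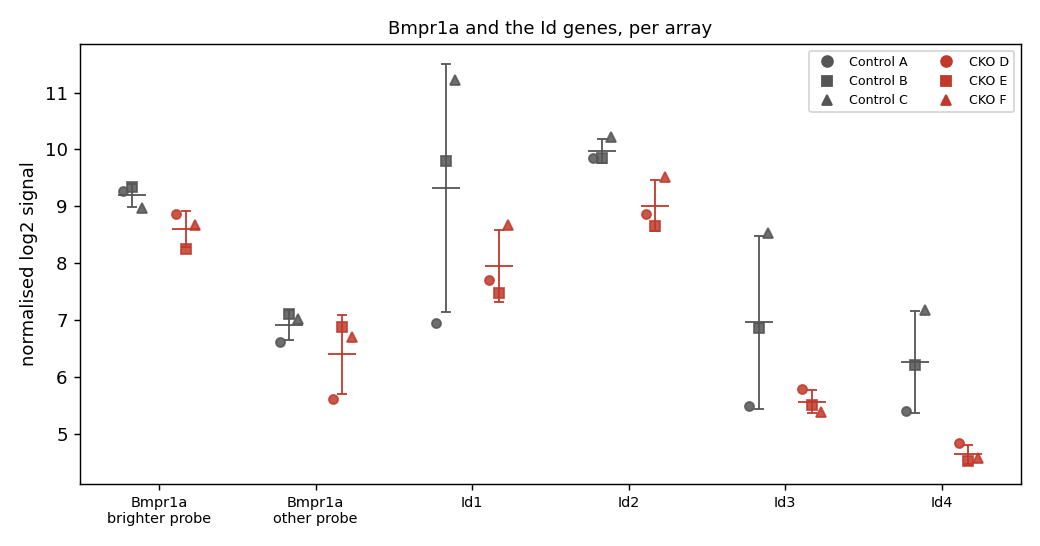
Normalised log2 signal (vertical axis) of both Bmpr1a probes and the main probes of Id1, Id2, Id3 and Id4 on each array; points are arrays, and bars are the group mean ± SD (n = 3). The brighter Bmpr1a probe averaged 8.60 in CKO and 9.19 in Control, and Id1 spread over an SD of 2.18 among Control arrays.

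Genes higher in CKO numbered 2 and genes lower numbered 0, by limma's adjusted p. Gin1, a gene related to retrotransposon integrases, rose from 4.73 ± 0.08 (SD, n = 3), below background on every Control array, to 7.33 ± 0.23 (SD, n = 3), at least 4.70-fold higher, with an adjusted p of 0.0351. Cops8, a subunit of the COP9 signalosome, rose from 5.21 ± 0.52 (SD, n = 3) to 8.60 ± 0.02 (SD, n = 3), a log2 difference of 3.39 (SE 0.27, adjusted p 0.0493), and was above background on 1 Control array. Gin1 had a pair of other probes that were below background on all 6 arrays and did not show the difference. Cops8 had a single probe. Cops8 alone passed without replicate A, and neither gene passed without any 1 of the other 5 arrays, although the difference of Cops8 stayed at 3.21 to 3.67. Without D, E or F, Gin1 was above background on too few arrays to be tested. Over all genes, 563 had an unadjusted p under 0.05, where 597 is what chance alone gives. The groups did not overlap for 10.6% of genes, against 10% by chance for 3 against 3.

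Several further genes had large differences with groups that did not overlap but did not pass. Erdr1 lay 2.56 higher in CKO on the log2 scale (SE 0.23, adjusted p 0.0628), and both of its probes were higher; it passed with a variance trend and robust fitting, and with array weights. Arrdc3 lay 2.45 higher (SE 0.28, adjusted p 0.186) and Thap4 1.39 higher (SE 0.16, adjusted p 0.186). Kit, a receptor tyrosine kinase, lay 2.21 higher (SE 0.35, adjusted p 0.586), another of its 3 probes lay 1.62 higher, and the last was below background on all arrays. Inmt, a methyltransferase, differed by -2.36 (SE 0.33, adjusted p 0.434) and both of its probes were lower in CKO. Cytip differed by -2.12 (SE 0.32, adjusted p 0.522) and Ccng2 by -1.09 (SE 0.18, adjusted p 0.695). The other 7 lower genes with the smallest p were Krt15 (-1.30), Atrnl1 (-0.98), Dnajb4 (-0.90), Mapk8ip1 (-0.89), Ero1b (-0.84), Polk (-0.83) and Acadm (-0.75), each a log2 difference with an adjusted p of 0.977. Of these, Krt15, Dnajb4 and Ero1b were above background on 1 CKO array each, so signal over background limits their differences. These shrank to as little as -0.62, -0.39 and -0.37 under the alternatives.

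**Figure D2:**
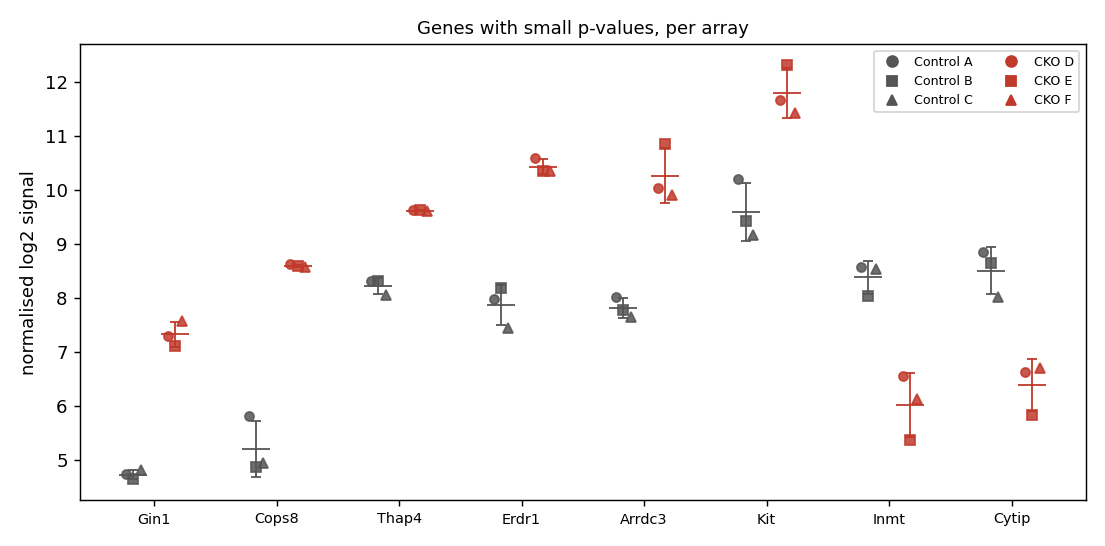
Normalised log2 signal (vertical axis) on each array for 8 genes; points are arrays, and bars are the group mean ± SD (n = 3). The groups do not overlap for any of the 8, and of these Gin1 and Cops8 passed the adjusted test.

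Of 21 genes listed as induced by BMP signalling, 10 were measured; 8 were lower and 2 higher in CKO, and 0 passed over all genes. Each function and marker list was also adjusted over its own members alone, without correction for the number of lists. A pass in some list can therefore arise by chance. Adjusted over this list alone, 2 members passed, and in no other list did any. These were Id2, with a log2 difference of -0.96 (SE 0.27) and all 3 probes lower, and Id4, above background on the 3 Control arrays and on 0 CKO arrays, at least 2.31-fold lower (adjusted p over the list 0.0468 for both). These calls were close to the threshold: that of Id2 was lost without any 1 of replicates A to E (0.0603, 0.200, 0.310, 0.161 and 0.123) and that of Id4 without D, E or F (0.161, 0.123 and 0.133), and Id4 was not tested without A, B or C. Id proteins are inhibitors of basic helix-loop-helix transcription factors. Id1 differed by -1.37 (SE 1.03) and Id3 by -1.40 (SE 0.70), with groups that overlapped; they were -2.56 and -2.12 without replicate A, and -0.42 and -0.61 without C. Msx1, a homeobox gene, differed by -0.34 (SE 0.34) by its main probe, from -0.56 without replicate D to -0.0091 without E. The other Msx1 probe, dimmer but above background on all arrays, differed by 0.064. The list as a whole was lower by camera with an adjusted p of 0.0105, but not with an estimated correlation (adjusted p = 0.560). Its mean deviation was -0.28, 0.35 and 0.88 on Control arrays A to C and -0.27, -0.55 and -0.13 on CKO arrays D to F. Control A lay below CKO D and F, so the groups overlapped. Without replicate A or F the camera call stood, and it was lost without B (adjusted p 0.108), C (0.327), D (0.0791) or E (0.108). The list of 23 measured BMP and TGF-beta ligands, receptors and SMADs had 9 members higher and 14 lower (adjusted p 0.780), and Chrd, a BMP antagonist, differed by 0.96 (SE 0.42).

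By camera, 3 function lists were higher in CKO. Immediate early and heat shock genes had 17 of 21 members higher (adjusted p 0.000839; adjusted p = 0.560 with an estimated correlation), with Atf3 at 0.96 (SE 0.26) and Zfp36 at 0.46 (SE 0.15). Cholesterol synthesis genes had 13 of 17 members higher (adjusted p 0.00367; adjusted p = 0.560 with an estimated correlation), with Srebf2 at 0.58 and Lss at 0.48 (SE 0.18 for both). Interferon-stimulated genes had 24 of 27 members higher (adjusted p 0.0267; adjusted p = 0.889 with an estimated correlation of 0.64), with Oas2 at 1.39 (SE 0.92) and Dhx58 at 0.96 (SE 0.54); with single arrays left out these ran from 0.61 to 2.20 and from 0.53 to 1.54. No member of these 3 lists passed over all genes or adjusted over the list alone. With an estimated correlation 0 of the 20 function lists were called, and by fry 0. The interferon call was lost without replicate B (adjusted p 0.333), C (0.930), E (0.723) or F (0.0925), and its mean deviation was as high on Control array A (0.71) as on CKO array E (0.71). The cholesterol call was lost without E (adjusted p 0.117) or F (0.0966), and the immediate early call without B (adjusted p 0.0935) or E (0.108).

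Genes of steroid response and implantation did not pass singly or as lists. Among estrogen-induced epithelial genes 17 of 26 were higher (adjusted p 0.239), among them Padi1 at 2.36 (SE 0.68) and Aqp8, a water channel, at 1.17 (SE 0.32). In the same list Ltf, which encodes lactoferrin, differed by -1.13 (SE 0.41), and Muc1, a surface mucin, by 0.77 (SE 0.33). Progesterone-induced genes had 11 of 19 higher (adjusted p 0.960), with Ihh at 1.20 (SE 0.48), Areg at 1.13 (SE 0.70) and Cited2 at -0.92 (SE 0.36). With single arrays left out these ran from 0.68 to 1.60, from 0.57 to 1.87 and from -1.17 to -0.50. Implantation and receptivity regulators had 16 of 27 higher (adjusted p 0.180). There Il6st differed by 0.80 (SE 0.29), and Lif, a cytokine needed for implantation, was below background in Control and at least 1.24-fold higher in CKO by its main probe. Another Lif probe, above background on 1 CKO array only, lay 0.58 higher. The remaining Lif probes were below background on all arrays, with differences of 0.061 to 0.078. Esr1, the estrogen receptor, differed by 0.42 (SE 0.34). Klf4 differed by 0.27 (SE 0.33), Klf5 by -0.10 (SE 0.17) and Klf3 by 0.93 (SE 0.31) in a list of Kruppel-like factors with 5 of 9 higher (adjusted p 0.372). Klf15 and Mki67 were above background on too few arrays to be tested.

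No list of the remaining functions was called with all arrays. Cell cycle genes had 14 members higher and 14 lower (adjusted p 0.960; called lower without replicate A, 0.00874), with Mcm2 at 0.54 and Top2a at 0.84. Cyclin-dependent kinase inhibitors had 6 of 7 lower (adjusted p 0.286), with Cdkn1b at -0.64, while Cdkn1a differed by 0.31 (SE 0.34). Growth factor signalling genes had 13 of 22 higher (adjusted p 0.881), with Fgf18 at -0.80 (SE 0.49). Junction and polarity genes had 16 of 29 higher (adjusted p 0.960), microvillus genes 5 of 14 (adjusted p 0.960) and mucins 3 of 5 (adjusted p 0.913). WNT pathway genes had 12 of 19 higher (adjusted p 0.557), with Wnt5a at 0.72 (SE 0.22). Channels and transporters had 6 of 18 higher (adjusted p 0.834), prostaglandin genes 1 of 11 (adjusted p 0.185; called lower without replicate A, 0.0404), matrix and protease genes 12 of 21 (adjusted p 0.960) and unfolded protein response genes 16 of 21 (adjusted p 0.239).

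With all arrays, 0 of the 13 marker lists differed between the groups by camera, with an estimated correlation or by fry. Camera called stroma and endothelium without replicate F, and mesothelium without replicate D. Stroma markers had the largest median log2 difference, 0.51 (adjusted p 0.212), with Col1a1 at 1.23 (SE 0.66) and Thy1 at 1.08 (SE 0.49). Their mean deviation was 0.74 on CKO array D, 0.93 on E and -0.95 on F, against -0.36 to -0.13 on Control arrays, so CKO samples lay on both sides of Control. Endothelium markers had mean deviations of 0.93 on array E and -0.77 on F (adjusted p 0.760). Median differences were -0.01 for pan-epithelial markers (adjusted p 0.996), -0.01 for luminal epithelium (adjusted p 0.996) and 0.14 for glandular epithelium (adjusted p 0.859). They were 0.01 for smooth muscle, 0.09 for macrophages and dendritic cells, -0.07 for lymphocytes, 0.22 for erythroid cells, 0.18 for the preimplantation embryo, -0.07 for mesothelium and -0.11 for ciliated epithelium. A single neutrophil marker was measured, at -0.18.

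**Figure D3:**
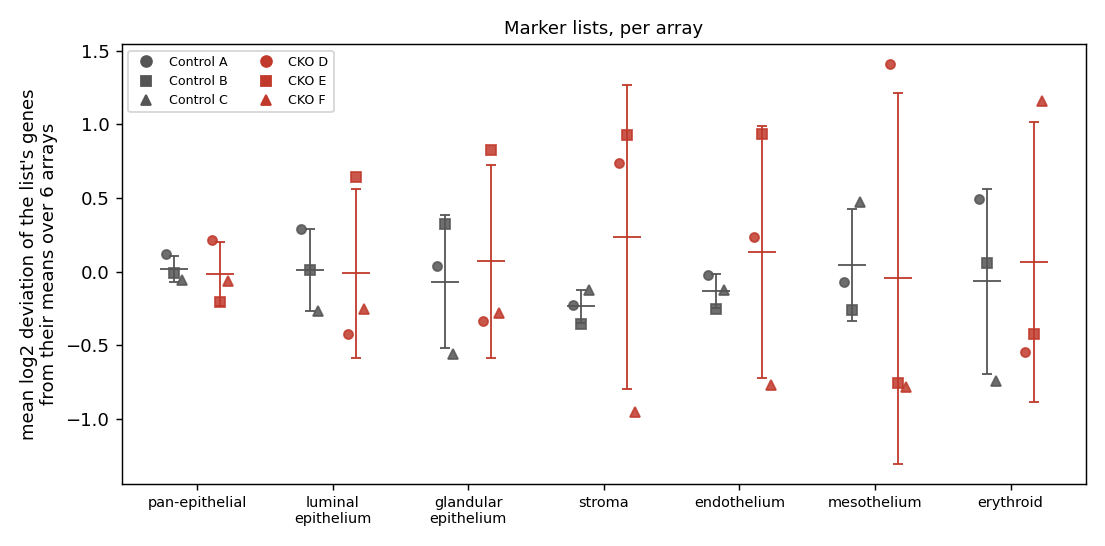
Mean log2 deviation of each marker list's genes from their means over the 6 arrays (vertical axis) for 7 lists; points are arrays, and bars are the group mean ± SD (n = 3). For stroma the CKO arrays lie at 0.74, 0.93 and -0.95, on both sides of Control.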

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

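The covariate fit was chosen after seeing the data; the other alternatives were planned. Genes lower in CKO stayed at 0 under all 17 alternatives, and Bmpr1a stayed negative and uncalled under all of them, from -0.73 to -0.43. Genes higher in CKO, 2 in the main setting, were 1 with normexp without controls, 1 with no background correction (Cops8 in both), 1 with cyclic loess and 1 with the deposited values (Gin1 in both). They were 0 with no filter, where 28865 genes shared the adjustment, 0 with the strict filter, which removes both genes, and 0 with the stroma covariate, which leaves 3 residual degrees of freedom. Array weights gave 5, adding Arrdc3, Erdr1 and Thap4, and a variance trend with robust fitting gave 3, adding Erdr1. Leaving out single arrays gave 0 to 1, and without D, E or F the filter removes Gin1. Lists higher were 0 with an estimated correlation, 0 with fry and 1 with no filter (immediate early genes), and 0 to 3 with single arrays left out. They were 2 with median scaling, the mean of probes and the stroma covariate, where the interferon call ended with adjusted p of 0.0516, 0.0767 and 0.0575. Lists lower were 0 with an estimated correlation, fry, no filter, the strict filter and array weights, and 0 to 3 with single arrays left out (cell cycle and prostaglandin genes added without A). Marker lists differing were 1 with the stroma covariate (macrophage and dendritic) and 0 to 2 with single arrays left out (mesothelium without D; stroma and endothelium without F).

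Of 92 other named genes, 80 kept their sign under every alternative run on them, and no called gene changed sign. Array weights turned Khdc3 to -0.0044, Klrd1 to -0.27, Ptgs1 to 0.076, Smtn to -0.41 and Wnt7a to -0.11, and the covariate turned Smtn to -0.087. With single arrays left out, 43 of the 92 kept their sign but moved by over 1.5 times, among them, of the genes given above, Areg, Cdkn1a, Chrd, Cited2, Col1a1, Dhx58, Esr1, Fgf18, Id1, Id3, Ihh, Klf3, Klf4, Klf5, Msx1, Muc1, Oas2, Padi1, Thy1 and Top2a. Another 9 changed sign: Pgr ran from -0.80 to 0.058, Hba-a1 from -0.26 to 0.77, Klrd1 from -0.085 to 0.61, Upk3b from -0.99 to 0.26 and Wnt7a from -0.11 to 0.60. Alas2 ran from -0.46 to 0.012, Upk1b from -1.30 to 0.27, Mylk from -0.60 to 0.26 and Mzb1 from -0.34 to 0.040. Adjusted over the BMP list alone, Id2 and Id4 both passed with cyclic loess, the deposited values and trend with robust fitting, Id4 alone with array weights and Id2 alone without F; neither passed under any other alternative, with adjusted p of up to 0.310. Except where a cause is named, the cause was not tested. Genes near background, such as Gin1 in Control, are limited by signal over background: its difference was 2.60 in the main setting and 1.40 with no background correction. Cops8, above background on 1 Control array, differed by 3.39 in the main setting. Its difference fell as low as 2.20 under another background correction or normalization.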

Other observations

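CKO array E stood apart from the other 5 arrays. On this array 687 genes were over 2-fold higher than the mean of the others and above each of them, and 767 were over 2-fold lower and below each; together these 1454 compare with 108 to 841 for any other array. Between the groups, 108 genes were over 2-fold apart with no overlap, where the other splits of the arrays into 3 and 3 gave 22 to 277. Against the mean of the others, Depp1 lay 6.38 higher on the log2 scale, Pcsk6 5.26, the serine protease gene Prss29 5.07 (Depp1 and Prss29 were above background on 2 of the other 5 arrays), Guca2b 4.73 and Cyp26a1, a retinoic acid hydroxylase, 4.19. For each of these genes another array was high too, so E lay closer to the next array than to that mean. The highest other array had 10.1 for Depp1 (12.4 on E), 9.24 for Pcsk6 (11.6) and 8.27 for Prss29 (10.5). It had 11.8 for Guca2b (13.4) and 12.4 for Cyp26a1 (13.6). Slc51a, below background on E, was at least 30.9-fold lower there than the mean of the others, whose lowest was 6.95. Gper1 lay at -4.54 on the log2 scale, Vldlr at -3.85 and Fgf1 at -3.50. These are values of 1 sample with no replicate. The first principal component held 51.7% of the variance and placed E at 65.7, with the other arrays from -39.7 to 17.7.

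The tests of array E, of the 3 genes on chromosome 1 and of the number of lists were all chosen after the result was seen; the tests of genes past the threshold were written before, except the one on raw signals. For array E, array quality was looked at by 3 measures (raw median, probes above background, beads per probe). On 0 of the 3 did E lie outside the range of the others. These measures do not gauge the quality of the RNA, so sample quality is not decided. Dilution of the epithelium by other cells is not decided for the lower genes. The pan-epithelial median was -0.074 (SD of members 0.90), so these markers as a set were not lower on E. The lower genes had a median of -1.33, but they were picked for lying over 2-fold lower, which fixed much of that gap. Stromal cells stay open for the higher genes: of the 3 most abundant stroma markers 2 were highest on E (Nt5e at 2.48 and Thy1 at 1.45 above the others), but Dcn, the most abundant, was at -0.25, and the stroma list's shift lay at the 84.2 percentile of random lists matched on mean and SD and at 99.91 matched on mean alone. Endothelial cells stay open too: their list lay 1.34 higher in median, at the 100 percentile (99.99 on mean alone), and of its 3 most abundant markers 2 were highest on E (Egfl7 at 1.43 and Vwf at 1.34 above the others), but Esam, the most abundant, was at 0.57 and not highest there. A different stage of the uterus at collection stays open as well and cannot be told apart from other cells by these lists. The implantation and receptivity list lay at the 99.99 percentile (100 on mean alone), and 6 of the 20 function lists exceeded 95 (11 on mean alone). Random lists were drawn gene by gene, as if genes varied independently. Lists whose genes vary together reach extreme percentiles more easily. The estimated correlation was 0.64 for endothelium, 0.68 for stroma and -0.00055 for the implantation list, so their percentiles cannot be compared. The glandular epithelium list lay 0.80 higher on E in median, at the 91.1 percentile (99.99 on mean alone). The luminal epithelium list lay 0.81 higher, at the 94.1 percentile (99.96 on mean alone). Whether the mix of epithelial cells differed on E was not tested.

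Gin1, Cops8 and Thap4, which ranked 1, 2 and 4 by p among 10240 placed genes, lie on chromosome 1 within a run of 35 tested genes (order of GRCm38.p6). Normalization is argued against, since even the smallest ratio of the lowest raw CKO to the highest raw Control signal was 1.94. Stromal content is not decided. Among CKO arrays the stroma marker mean ranged over 3.96 times its difference from Control, but the 3 genes over at most 0.20 times theirs. For this, Control signals below background were set to the lowest above it. The 3 genes did not follow the stroma markers among CKO arrays. But they were picked by small p, which favours a small spread against the difference and fixed much of that gap. With the stroma covariate, which leaves a residual degree of freedom fewer, adjusted p became 0.416 for Cops8 (3.38, SE 0.32, from 3.39, SE 0.27) and 0.133 for Gin1, which has only a bound in Control. A block of strain-derived DNA that differs between the groups may be involved, as the background was mixed, and 2 tests do not decide it. In a scan of windows of 51 neighbouring genes the highest count with an unadjusted p under 0.01 was 3. Of the shuffles 92.9% reached that count, so a block of only these 3 genes could not have stood out in the scan. Random draws held 3 genes as close together in 0.028% of draws of 5 genes, 0.333% of 10, 3.25% of 20 and 40.1% of 50. That second test took its span from these genes after they were noticed, and its value depends on the number drawn. An effect of the CKO itself stays open and untested.

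For the 2 genes past the threshold, strain DNA at the engineered loci and array brightness were argued against. Other cell types were not decided. Of 6 non-epithelial lists 0 had array means that were apart between the groups, but 1 array is enough to make groups overlap. The stroma list, with a median difference of 0.51, overlapped only through CKO array F at -0.95. Of neutrophil and lymphocyte markers, 1 and 5 were measured. For stromal cells alone, the 2 genes did not follow the stroma markers among CKO arrays, but their choice by small p favours this. DNA of the 129S5/SvEvBrd strain around the Pgr-Cre knock-in or the floxed Bmpr1a allele: 0 of the 2 genes lay within 20 Mb of Pgr and 0 within 20 Mb of Bmpr1a, where 92 and 133 genes were tested; with 2 genes this speaks only to those 2. A difference in array brightness: the lowest raw CKO signal was at least 2.29 times the highest raw Control signal for both genes, where any 2 arrays differed by at most 1.21 times at 6 quantiles of raw signal and in the mean. Raw medians did not overlap (79.7 to 82.1 in CKO, 82.4 to 87.6 in Control), and the sign changes looked for beforehand (0 of the 2 genes) decide nothing, since such gaps are too small to turn these differences.

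With 10 splits of the 6 arrays no share under 0.05 can be reached. The real split gave 2 genes and the highest other split 0, so 1 of 10 gave as many. The real split gave 4 lists and the highest other split 5, and 5 of the 10 splits gave at least 4.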
